A study of Mus musculus with 6 samples.

How the data were processed

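The data are 1 table of read counts per gene for 6 spinal cord RNA samples of wild-type mice. The samples were taken 6 weeks after a contusion injury at thoracic level T10, and all carry the same batch label. Per the labels' protocols, magnetic beads were used to isolate total RNA, which was sequenced as paired-end reads on an MGI DNBSEQ-T7 instrument. The table holds raw read counts as deposited by the authors, whole numbers that had not been normalised, with 1 column per sample. Replicates were not pooled. The submitters' processing notes name fastp 0.23.0 and HISAT2 2.1.0. The counting program, its strand setting, its treatment of reads that map to several places, the genome build and the annotation release are not given in the sources used here.

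Columns were assigned to samples by the library names in the labels, and samples to groups by the treatment given in their titles, 3 in the injury group and 3 in the injury + AZ876 group. The labels do not say that the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part. The table has 57010 rows. A total of 148 gene symbols stood on more than 1 row, and the counts of all 148 were identical on each of their rows, so 1 row per symbol was kept, which left 56859 genes. Of these, 32377 had at least 1 count. A further check concerned the headers of the annotation columns: the column headed as molecular function held the cellular component root term in 4293 rows and the column headed as cellular component in 0, so the 2 headers were exchanged before terms were used. Gene positions in the table were compared with GENCODE M21 on GRCm38: of 51967 genes matched by identifier, 2.80% had the same start. The table therefore uses another build or annotation, which it does not name, and positions are printed as the table gives them.

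Total counts per library were 20211175, 19506553 and 15493073 for injury replicates 1, 2 and 3, and 14219862, 14067649 and 17676466 for AZ876 replicates 1, 2 and 3. Chi-square tests of the counts gave 13.1 to 120 per degree of freedom for pairs of libraries, over genes with at least 20 counts in the pair, so no library was a copy of another. Low-count genes were removed with edgeR's filterByExpr by group, which left 17599 genes, 15015 of them protein-coding. Libraries were scaled by TMM, and CPM values, counts scaled to the same library size, were computed from the TMM-scaled sizes. The test was edgeR's robust quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) of AZ876 against injury with no covariates and 4 residual degrees of freedom, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change is the fold change divided by the square root of the F statistic. Where log2 CPM was used, the prior count was 2. Single values were compared by two-sided exact permutation tests over the 20 assignments of 3 labels to 6 libraries, which cannot give a p below 0.1. Principal components were computed on centred log2 CPM.

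Before the data were examined, 54 gene lists for lipid metabolism, myeloid, immune, glial, neuronal, scar, vascular and other-tissue genes were fixed. They hold 1148 distinct genes, of which 1141 were found in the table and 1066 were tested, and 52 lists had the 5 tested members needed for a set test. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with a correlation estimated for each list, and with fry, each with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes, and fry asks whether a list's genes move on balance 1 way. A list score is the mean log2 CPM of the tested members after centring each gene on its mean over the 6 libraries. Members were also adjusted over the list alone, with no further adjustment for the number of lists. Terms of the table's own gene annotation with 15 to 300 tested genes were tested with camera in the same way, within each annotation source.

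Genes are named by a rule set at the same time. Abca1, Abcg1 and Apoe are given in all cases. If no gene passed, the 10 genes of smallest p in each direction with a mean of at least 1 CPM follow, passing over predicted genes, together with the 2 members of smallest p of a list. Genes past the threshold would have been taken first, by the size of the change. Some genes that the rule takes are not reported here. Any gene outside the rule is said to be chosen after its values were seen.

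Before use, the tests were run on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 200 of 17354 genes changed. In that simulation of AZ876 against injury, edgeR called 9.09% of genes changed 1.5-fold, 37.5% of those changed 2-fold and 89.9% of those changed 4-fold. Of its 96 calls 2 were unchanged genes. DESeq2 made 156 calls, of which 43 were unchanged genes, and limma-voom made 87, of which 1 was. With 1 list raised 1.5-fold, camera with an estimated correlation gave it an adjusted p of 0.0220 and fry one of 0.0224, and no list was called when none was changed. Each gene was drawn independently, so the simulation held no correlation between the genes of a list. It therefore cannot show how often the list tests call or miss a list whose genes move together.

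The alternatives fixed with the lists and the rule were other scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a block, each library left out in turn, a fold-change minimum, and the other set tests. Thinning all libraries to the smallest total, and leaving out each library for the counts adjusted over a list alone, were added after seeing the data. Immunoglobulin, haemoglobin, T cell receptor and MHC genes have near-identical relatives, and their counts are uncertain to the extent that reads were shared between copies. Without a stated strand setting, overlapping genes on opposite strands cannot be told apart.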

Results

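Messenger RNA levels were measured by sequencing in spinal cord tissue of mice 6 weeks after a contusion injury at thoracic level T10. In the injury + AZ876 group (n = 3), mice had received AZ876, an agonist of the liver X receptors (LXR), by intraperitoneal injection at 5 mg/kg once daily for 1 week after the injury. In the injury group (n = 3), no AZ876 was given, and the labels' protocols state that control animals received the solvent. LXR are nuclear receptors activated by oxidised cholesterol that switch on genes of cholesterol export. The libraries held between 14067649 and 20211175 counts, and the 10 most abundant genes took 8.21% to 10.9% of them. The most abundant gene was Mbp, a myelin protein gene, in injury replicate 1, the mitochondrial gene mt-Co1 in injury replicate 2 and AZ876 replicate 1, and Apoe in the remaining 3 libraries.

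The comparison of injury + AZ876 with injury asked how treatment in the first week changed lipid metabolism genes over the long term, with cholesterol efflux as the focus of the study. At 6 weeks, Abca1, Abcg1 and Apoe had mean levels 1.62, 1.45 and 1.37 times as high in the AZ876 group as in the injury group (log2 fold changes of 0.69 ± 0.33, 0.53 ± 0.21 and 0.46 ± 0.27, SE, n = 3 each), but the libraries of the groups overlapped for each of them and none of the 3 genes passed the test. The mean scores of the lists for T and natural killer cells, MHC class II, fibroblasts and meninges, scar matrix and Schwann cells were higher in each of the 3 AZ876 libraries than in any injury library, though not every member was. The mean scores of the neuron, synaptic and transmission lists were lower on average with AZ876, with AZ876 replicate 1 among the injury libraries, while the motor neuron score was lower in each AZ876 library than in any injury library. Of the 17599 genes tested, edgeR and limma-voom called 0 at an adjusted p under 0.05, and DESeq2 called 124 higher and 54 lower, while 1405 were higher and 1187 lower in edgeR at an unadjusted p under 0.05. DESeq2 calls here and below are less strict: in the simulation 43 of its 156 calls were unchanged genes, against 2 of 96 for edgeR.

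Abca1 encodes the transporter that loads cellular cholesterol onto lipid-poor apolipoproteins. It is listed as ENSMUSG00000015243, a protein-coding gene on the minus strand of chromosome 4 from 53030787 to 53159895, in a build that the table does not name. In counts scaled to library size (CPM), its level was 271 ± 89.7 CPM in the injury group and 438 ± 155 CPM in the AZ876 group (SD, n = 3 each). The log2 fold change was 0.69 ± 0.33 (SE), with an adjusted p of 0.352 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Abcg1 encodes a transporter that exports cholesterol to mature HDL particles and is listed as ENSMUSG00000024030, a protein-coding gene on the plus strand of chromosome 17 from 31276649 to 31336962. It had 142 ± 29.0 CPM in the injury group and 205 ± 50.1 CPM in the AZ876 group, a log2 fold change of 0.53 ± 0.21 (SE) with an edgeR adjusted p of 0.330. Apoe encodes apolipoprotein E, the main lipid carrier made by glia and macrophages in the nervous system. It is listed as ENSMUSG00000002985, a protein-coding gene on the minus strand of chromosome 7 from 19430034 to 19433113. Its level was 17588 ± 3719 CPM with injury and 24114 ± 7402 CPM with AZ876, a log2 fold change of 0.46 ± 0.27 (SE) with an edgeR adjusted p of 0.422. Two-sided exact permutation tests of log2 CPM gave p = 0.3 for Abca1, p = 0.2 for Abcg1 and p = 0.3 for Apoe, where 0.1 is the smallest p that 3 against 3 samples allow. The direction was the same when any 1 library was left out. The log2 fold change then ranged from 0.43 to 0.93 for Abca1, from 0.33 to 0.71 for Abcg1 and from 0.25 to 0.68 for Apoe, lowest in each case without AZ876 replicate 3, and the highest values came without AZ876 replicate 1 for Abca1 and Apoe and without injury replicate 3 for Abcg1.

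**Figure D1:**
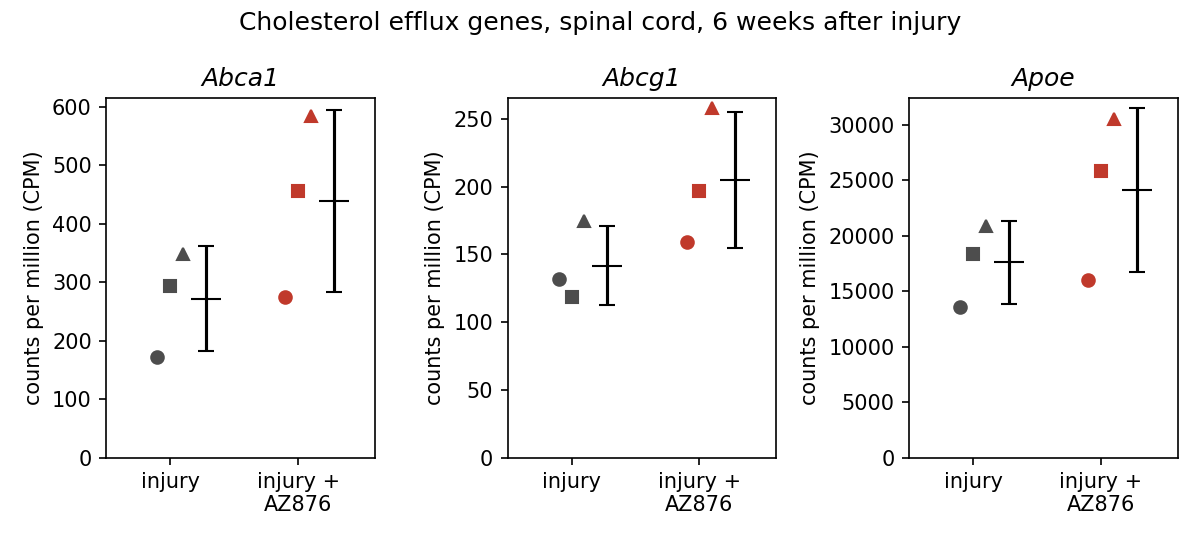
Levels of Abca1, Abcg1 and Apoe in CPM (vertical axes, starting at 0) in each library of the injury group (grey) and the injury + AZ876 group (red), where circles, squares and triangles are replicates 1, 2 and 3 and the bars give the mean ± SD of 3 libraries. AZ876 replicate 1, at 275 CPM for Abca1, lies within the range of the injury libraries for each gene.

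LXR target genes, a list that includes Abca1, Abcg1 and Apoe, were somewhat higher on average with AZ876: 19 of 23 tested members had a positive log2 fold change, with a median of 0.29, and 5 higher and 1 lower had an unadjusted p under 0.05. The list scores of the groups overlapped, with AZ876 replicate 1 at −0.12 and injury replicate 3 at 0.06 (exact permutation p = 0.2). Smpdl3a, a cholesterol-responsive phosphodiesterase gene, was at 51.4 ± 8.44 CPM with injury and 77.6 ± 14.3 CPM with AZ876. Lpl, which encodes lipoprotein lipase, was at 141 ± 32.0 CPM and 265 ± 96.2 CPM. The 6 LXR targets that are also on the fatty acid synthesis list, a group chosen after the values were seen, went both ways: the log2 fold change was −0.31 for Fasn, −0.27 for Acaca, −0.07 for Scd2, 0.10 for Scd1, 0.27 for Srebf1 and 0.29 for Mlxipl. Camera placed the list higher with an adjusted p of 0.00588 at the preset correlation. Its adjusted p = 0.478 with an estimated correlation, and without injury replicate 1 or AZ876 replicate 3 the preset camera adjusted p was 0.0877 and 0.0886. Adjusted over the list alone by Benjamini-Hochberg, edgeR called 0 members, as did DESeq2 and limma-voom, while edgeR called 3 members without injury replicate 3 and 8 without AZ876 replicate 1.

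The reverse cholesterol transport list, which also includes Abca1, Abcg1 and Apoe, had 21 of 29 members higher, with a median log2 fold change of 0.20. Its scores overlapped too, with AZ876 replicate 1 at −0.07 and injury replicate 3 at 0.01 (exact permutation p = 0.2). Cav1, which encodes the caveolae protein caveolin-1, was at 51.2 ± 11.2 CPM with injury and 89.5 ± 7.62 CPM with AZ876, and Abca2, a transporter gene of oligodendrocytes, at 667 ± 142 CPM and 426 ± 11.7 CPM. Cholesterol synthesis genes leaned the other way: 20 of 24 had a negative log2 fold change, with a median of −0.18. Insig1, a feedback regulator of the sterol pathway, was at 54.6 ± 12.5 CPM with injury and 37.4 ± 1.83 CPM with AZ876. Preset camera gave adjusted p-values of 0.00896 for reverse cholesterol transport and 0.0105 for cholesterol synthesis, and with an estimated correlation the adjusted p-values were 0.438 and 0.497. The call for reverse cholesterol transport was lost without AZ876 replicate 3 (camera adjusted p of 0.0518), and that for cholesterol synthesis without injury replicate 1 (0.288) or AZ876 replicate 1 (0.0661). Adjusted over the list alone, edgeR called 0 members of either list, where 8 and 0 were higher and 1 and 4 lower at an unadjusted p under 0.05. DESeq2 called 3 higher and 1 lower and limma-voom 1 higher for reverse cholesterol transport, and neither called any for cholesterol synthesis. In edgeR, reverse cholesterol transport had 12 higher and 3 lower without AZ876 replicate 1, 5 higher and 1 lower without injury replicate 3 and 1 higher without injury replicate 2, and cholesterol synthesis had 1 lower without injury replicate 3.

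Scavenger receptor genes had 14 of 17 members higher, with a median of 0.60 and a preset camera adjusted p of 0.000108, or 0.430 with an estimated correlation. Cd36, a receptor for fatty acids and oxidised lipoproteins, was at 7.76 ± 6.30 CPM with injury and 39.0 ± 20.1 CPM with AZ876. The fatty acid oxidation, lipid droplet and fatty acid synthesis lists did not pass, with preset camera adjusted p-values of 0.157, 0.196 and 0.381, although fatty acid oxidation passed without injury replicate 3 (0.0409). All 26 tested markers of disease-associated and foamy myeloid cells had a positive log2 fold change, with a median of 0.63, a preset camera adjusted p of 1.44e-10 and one of 0.430 with an estimated correlation. The foamy myeloid scores of the groups overlapped, with AZ876 replicate 1 at −0.22 and injury replicate 3 at 0.03 (exact permutation p = 0.2). Igf1, a growth factor gene, was at 76.2 ± 16.8 CPM with injury and 170 ± 42.1 CPM with AZ876. Adjusted over the list alone, 1 foamy myeloid member passed in edgeR, against 25 without AZ876 replicate 1, 8 without injury replicate 3 and 0 without any 1 of the other libraries, and 1 scavenger receptor member passed, against 7, 6 and 0. DESeq2 and limma-voom called 7 and 2 foamy myeloid and 5 and 2 scavenger receptor members over the list alone.

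Of the 20 genes of smallest p taken by the naming rule, 10 in each direction, 0 passed the threshold over all genes in edgeR with low-count genes removed. In DESeq2 18 of them passed it, all but Ighg1 and Pde6b. With no low-count filter Ighg1, Scn7a, Slc6a20a, Anxa1 and Zic2 passed it in edgeR. Ighg1, an immunoglobulin heavy chain gene, was at 0.165 ± 0.0522 CPM with injury and 2.38 ± 0.484 CPM with AZ876, a log2 fold change of 3.80 ± 0.41 (SE) with an edgeR adjusted p of 0.295, the smallest of all genes. Cd74, the invariant chain of MHC class II, was at 119 ± 33.9 and 288 ± 33.1 CPM, a log2 fold change of 1.27 ± 0.21. Tfpi, a coagulation inhibitor gene, had a log2 fold change of 0.87 ± 0.14, Anxa1, which encodes annexin A1, 1.15 ± 0.20, and Grem1, which encodes a secreted BMP antagonist, 1.46 ± 0.25. Scn7a and Ncmap, both expressed in Schwann cells, had 1.15 ± 0.19 and 0.68 ± 0.12. The remaining genes on the higher side were Slc6a20a (1.14), Zic2 (1.00) and Atp8b4 (1.83). On the lower side, Pvalb, the gene of the calcium buffer parvalbumin, was at 76.9 ± 13.9 CPM with injury and 40.0 ± 9.01 CPM with AZ876, a log2 fold change of −0.94 ± 0.20. The sodium channel subunit gene Scn4b had a log2 fold change of −1.23 ± 0.27, and Hcn2, a pacemaker channel gene, had −0.72 ± 0.16. Rab37 (−0.67), Myh14 (−0.55), Pde6b (−2.03), Car7 (−0.97), Cdh22 (−0.73) and Ifitm10 (−0.66) were also lower. For all 20 genes the 3 libraries of each group did not overlap. They were picked by smallest p in the same libraries, so neither this nor their calls under other settings are independent support.

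In edgeR, 2592 genes had an unadjusted p under 0.05, where chance gives about 880. The groups did not overlap for 1791 higher and 1521 lower genes, or 18.8% of genes, where chance gives 10% on average. Both numbers vary widely when the 6 libraries are divided into 3 and 3 in all 10 ways. The share without overlap then ran from 4.35% to 31.3%, and the genes at an unadjusted p under 0.05 in edgeR from 121 to 4620. Neither number therefore shows a difference beyond chance. The count of 2592 genes became 1290 without injury replicate 1, 1588 without injury replicate 2, 4038 without injury replicate 3, 4634 without AZ876 replicate 1, 986 without AZ876 replicate 2 and 1066 without AZ876 replicate 3. Without AZ876 replicate 1, edgeR called 64 genes higher and 299 lower at an adjusted p under 0.05, and 11 of the 20 genes of smallest p were among them. On the first principal component, which held 55.4% of the variance, AZ876 replicate 1 stood at −7.17 and injury replicate 3 at 6.31, between the other injury libraries at −40.6 and −52.3 and the other AZ876 libraries at 44.2 and 49.5.

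**Figure D2:**
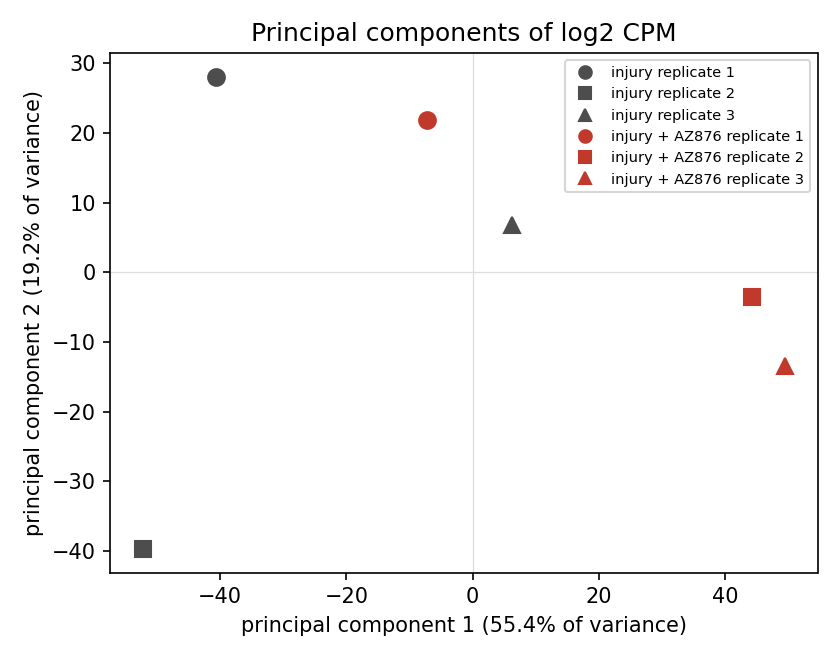
First and second principal components of log2 CPM over the tested genes, with the share of variance on each axis, where grey symbols are injury libraries, red symbols injury + AZ876 libraries, and circles, squares and triangles are replicates 1, 2 and 3. AZ876 replicate 1 (−7.17) and injury replicate 3 (6.31) lie next to each other in the middle of the first component.

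Several lists of immune cells and functions were higher with AZ876, though dendritic cell markers, 8 of 13 of them higher, did not pass preset camera (adjusted p of 0.184) except without injury replicate 3 (0.0303). All 19 tested markers of T and natural killer cells had a positive log2 fold change, with a median of 1.5. In edgeR 13 passed when adjusted over the list alone, which takes no account of the number of lists, and 0 passed over all genes. Trbc1, a T cell receptor gene, was at 0.720 ± 0.112 CPM with injury and 2.22 ± 0.412 CPM with AZ876, and Cxcr6, a chemokine receptor gene of tissue-resident T cells, at 1.13 ± 0.429 and 3.82 ± 1.38 CPM. All 15 genes of antigen presentation by MHC class II were higher, with a median of 0.89, and 11 passed over the list alone. Besides Cd74, H2-Ab1, a class II chain gene, was at 51.1 ± 20.7 CPM with injury and 132 ± 14.7 CPM with AZ876. DESeq2 and limma-voom called 12 and 14 of the T and natural killer cell markers, 11 each of the MHC class II genes and 8 each of the complement genes over the list alone. All 17 complement genes were higher, with a median of 0.79 and 6 past the threshold over the list alone, and C1s1, which encodes a protease of the classical pathway, was at 12.5 ± 3.86 and 32.4 ± 11.4 CPM. The complement scores of the groups overlapped, with AZ876 replicate 1 at −0.08 and injury replicate 3 at 0.01 (exact permutation p = 0.2). Preset camera gave adjusted p-values of 7.01e-14 for T and natural killer cells, 7.30e-14 for MHC class II and 1.03e-09 for complement, and each had an adjusted p of 0.430 with an estimated correlation. The edgeR counts over the list alone depended on single libraries. For T and natural killer cells the count was 0 without injury replicate 1, injury replicate 2 or AZ876 replicate 2, and for MHC class II it was 6 without AZ876 replicate 2 and 7 without AZ876 replicate 3. For complement it was 1 without injury replicate 1, 15 without AZ876 replicate 1, and 0 without injury replicate 2, AZ876 replicate 2 or AZ876 replicate 3.

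Markers of infiltrating monocytes and macrophages had 17 of 19 members higher with a median of 0.85, where Mrc1, the mannose receptor gene, was at 17.8 ± 4.53 and 40.4 ± 8.98 CPM. The preset camera adjusted p was 2.65e-08, and 0.430 with an estimated correlation. Over the list alone, edgeR called 1 member, DESeq2 10 and limma-voom 8, and edgeR called 0 without AZ876 replicate 2 or AZ876 replicate 3, 2 without injury replicate 1 or injury replicate 2, 6 without AZ876 replicate 1, and 12 higher and 1 lower without injury replicate 3. Homeostatic microglia markers had a median of 0.23 and did not pass preset camera (adjusted p of 0.0963), but did without injury replicate 3 (0.0181) or AZ876 replicate 1 (0.00925). Siglech, a lectin gene of homeostatic microglia, was at 15.6 ± 2.08 CPM with injury and 10.1 ± 2.01 CPM with AZ876.

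The mean scores of the fibroblast, scar matrix and Schwann cell lists were also higher in each of the 3 AZ876 libraries than in any injury library. All 23 tested fibroblast and meninges markers had a positive log2 fold change, with a median of 0.84, and 13 passed over the list alone. Mgp, which encodes matrix Gla protein, was at 170 ± 24.9 CPM with injury and 267 ± 28.8 CPM with AZ876. Of 38 fibrotic scar matrix genes, 37 were higher, with a median of 0.68, and 13 passed over the list alone. Ccn2, the connective tissue growth factor gene, was at 62.5 ± 12.4 and 110 ± 4.43 CPM, and Lama2, a laminin chain gene, at 29.3 ± 2.68 and 43.8 ± 1.52 CPM. Of 18 Schwann cell markers, 16 were higher, with a median of 0.68, and 10 passed over the list alone, with Scn7a at 23.9 ± 5.14 and 53.0 ± 8.08 CPM. DESeq2 and limma-voom called 18 and 16 fibroblast, 25 and 20 scar matrix and 13 and 12 Schwann cell markers higher over the list alone, and DESeq2 called 2 Schwann cell markers lower. Preset camera gave adjusted p-values of 1.07e-16 for scar matrix, 7.01e-14 for fibroblasts and meninges and 7.53e-11 for Schwann cells, and each had an adjusted p of 0.430 with an estimated correlation. Over the list alone, the fibroblast count was 0 without injury replicate 2 or AZ876 replicate 2, 3 without AZ876 replicate 3, 7 without injury replicate 1 and 8 without AZ876 replicate 1. The scar matrix count was 0 without AZ876 replicate 2 or AZ876 replicate 3 and 22 without injury replicate 3, and the Schwann cell count was 5 without AZ876 replicate 2 and 6 without AZ876 replicate 3.

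The chondroitin sulfate proteoglycan list, with 10 members higher and 11 lower, did not pass preset camera (adjusted p of 0.197). Over the list alone, 3 members passed higher and 6 lower in edgeR, as in DESeq2 and limma-voom, and in edgeR 0 passed without injury replicate 1, injury replicate 2, AZ876 replicate 2 or AZ876 replicate 3. The lower members included Hapln2, a link protein gene of nodes of Ranvier, at 208 ± 41.8 and 127 ± 11.7 CPM, and Acan, the perineuronal net core protein gene, at 15 ± 1.94 and 7.06 ± 2.79 CPM.

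**Figure D3:**
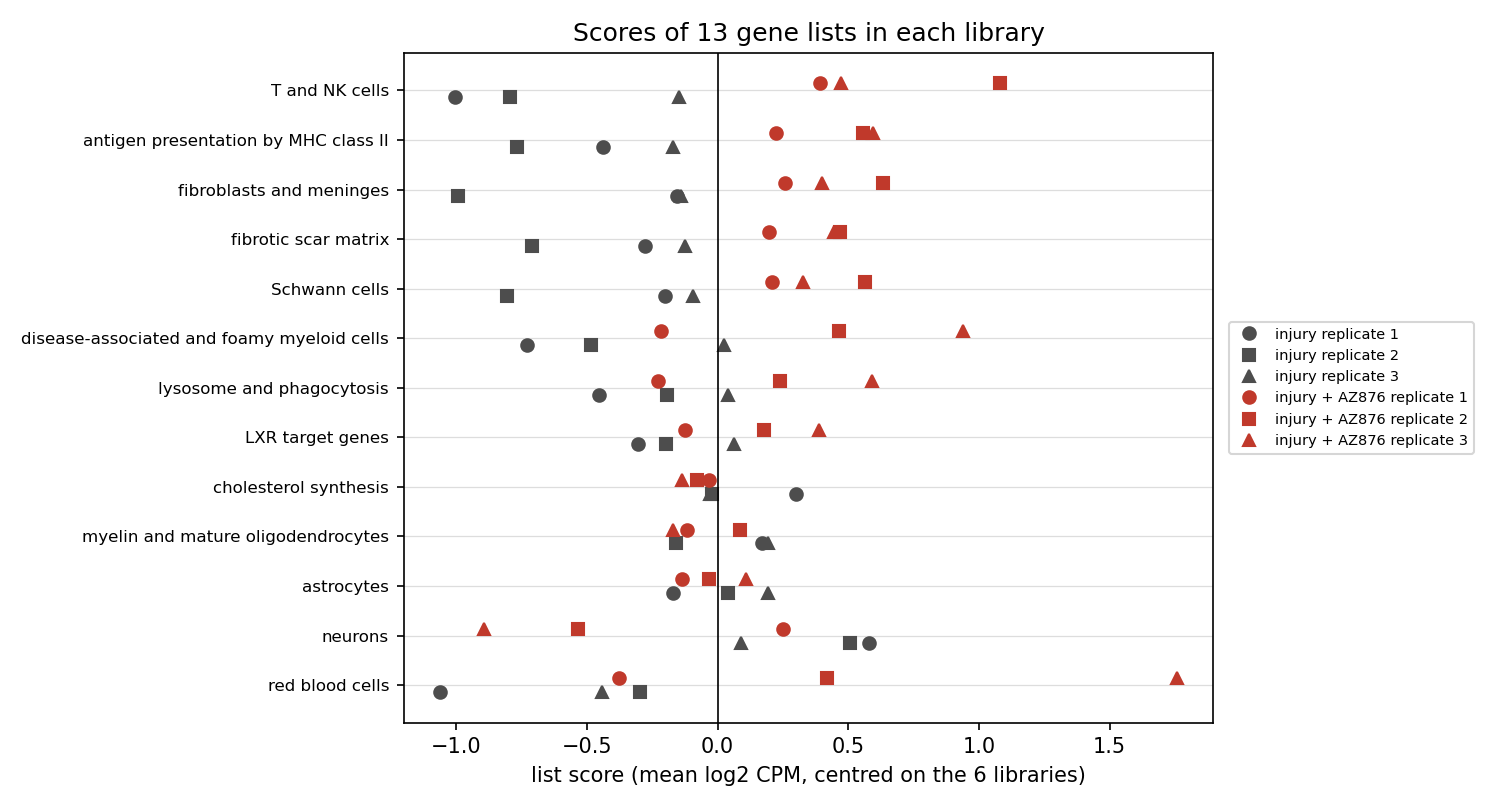
Scores of selected gene lists in each library, where the horizontal axis is the mean log2 CPM of a list's genes centred on the 6 libraries, grey symbols are injury libraries, red symbols injury + AZ876 libraries, and circles, squares and triangles are replicates 1, 2 and 3. For T and natural killer cells the AZ876 libraries lie between 0.39 and 1.08 and the injury libraries between −1.0 and −0.15, while for neurons AZ876 replicate 1 (0.25) lies among the injury libraries.

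Neuronal genes were lower on average with AZ876. All 24 neuron markers had a negative log2 fold change, with a median of −0.75, and 13 had an unadjusted p under 0.05. Nefm, which encodes a neurofilament subunit, was at 1452 ± 145 CPM with injury and 722 ± 265 CPM with AZ876, and Uchl1, a neuronal deubiquitinase gene, at 356 ± 67.9 and 206 ± 56.0 CPM. Of 30 synaptic genes 29 were lower, with a median of −0.67, and of 28 genes of glutamatergic and inhibitory transmission 26 were lower, with a median of −0.63. Slc32a1, the vesicular transporter gene of GABA and glycine, was at 97.6 ± 9.11 and 49.7 ± 23.1 CPM. All 14 motor neuron markers were lower, with a median of −0.57, and the scores of this list were −0.04, 0.01 and −0.87 in the AZ876 libraries against 0.31, 0.48 and 0.12 in the injury libraries (exact permutation p = 0.1). Preset camera gave adjusted p-values of 1.13e-13 for neurons, 8.82e-11 for synaptic genes, 7.89e-08 for transmission and 3.04e-05 for motor neurons, and each had an adjusted p of 0.430 with an estimated correlation. Over the list alone, 0 neuron markers passed in edgeR, 16 in DESeq2 and 14 in limma-voom, and in edgeR 23 passed without AZ876 replicate 1, 6 without injury replicate 3 and 2 without AZ876 replicate 3. The neuron score of AZ876 replicate 1 was 0.25, against 0.58, 0.51 and 0.09 in the injury libraries and −0.54 and −0.89 in the other AZ876 libraries.

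Among glial markers, of 30 myelin and mature oligodendrocyte genes, 23 were lower with a median of −0.16 and a preset camera adjusted p of 0.00544, which was 0.478 with an estimated correlation, and the call was lost without injury replicate 3 (0.123) or AZ876 replicate 1 (0.141). Myrf, the transcription factor gene of myelination, was at 223 ± 19.9 CPM with injury and 162 ± 16.9 CPM with AZ876. Astrocyte markers had a median of 0.01, with 9 higher and 9 lower, and passed camera as lower without injury replicate 1 alone (adjusted p of 0.0347), while 25 of 26 reactive astrocyte genes were higher with a median of 0.56, a preset camera adjusted p of 1.97e-08 and one of 0.430 with an estimated correlation. The reactive astrocyte scores of the groups overlapped, with AZ876 replicate 1 at −0.08 and injury replicate 3 at 0.01 (exact permutation p = 0.2). Cp, which encodes the ferroxidase ceruloplasmin, was at 132 ± 33.5 and 281 ± 63.7 CPM. Oxidative phosphorylation genes were lower in 42 of 44 cases with a median of −0.28, a preset camera adjusted p of 3.11e-09 and one of 0.430 with an estimated correlation. Red blood cell genes were higher, with a median of 1.57 over 11 members, a preset camera adjusted p of 1.08e-05 and one of 0.430 with an estimated correlation, and haemoglobin transcripts took 1.6% of the counts of AZ876 replicate 3, against 0.178% to 0.460% in the other 5 libraries. The red blood cell scores overlapped too, with AZ876 replicate 1 at −0.38 and injury replicate 2 at −0.30 (exact permutation p = 0.2). Skeletal muscle and dorsal root ganglion neuron markers did not pass preset camera, with adjusted p-values of 0.868 and 0.563.

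In all, preset camera placed 27 of the 52 tested lists higher and 8 lower with AZ876. With an estimated correlation 0 lists passed, 4 had an unadjusted p under 0.05 and the smallest camera adjusted p was 0.430. Those 4 lists were fibrotic scar matrix, MHC class II, T and natural killer cells, and infiltrating monocytes and macrophages. Fry also called 0, with a smallest adjusted p of 0.136.

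The table's own annotation terms gave a like division. Among 887 biological process terms of the Gene Ontology, preset camera placed 66 higher and 80 lower, led by immune response (median log2 fold change 0.61, adjusted p of 4.23e-12) and by chemical synaptic transmission (median −0.53, adjusted p of 5.20e-08). Among 365 cellular component terms 25 were higher and 63 lower, with collagen-containing extracellular matrix (0.36) and axon initial segment (−0.53) in the lead. Among 491 molecular function terms 54 were higher and 33 lower, led by chemokine activity (0.87) and monoatomic ion channel activity (−0.47). Among 317 KEGG pathways 96 were higher and 40 lower, led by Hematopoietic cell lineage (0.57) and Oxidative phosphorylation (−0.24). With an estimated correlation 0 terms passed in any of the 4 sources, and the smallest camera adjusted p-values were 0.825, 0.735, 0.772 and 0.551.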

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

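All alternatives were planned except thinning to the smallest library total and leaving out libraries for the counts over a list alone and for the differences between list scores, which were chosen after seeing the data. The number of genes higher with AZ876 in edgeR at an adjusted p under 0.05 was 0. It was 6 with no low-count filter, 5 of them among the named genes, and 124 in DESeq2. Leaving out 1 library gave a range of 0 to 64 higher genes and of 0 to 299 lower genes, with both maxima without AZ876 replicate 1. The number of genes lower was 54 in DESeq2 and 0 under every other setting that kept all libraries. Whether same-numbered libraries share more than a number is not known: the deviations of same-numbered libraries from their group means correlated at 0.390, −0.137 and 0.322, and not every library correlated best with its own number. These values neither establish nor exclude a pairing. With the replicate block, 2 genes were higher, Cd5l and Atp6v0d2, named here after their values were seen, and 0 were lower. At an unadjusted p under 0.05 in edgeR, the block gave 1981 genes higher and 1992 lower. Lists higher were 27 and lists lower 8 in camera at the preset correlation, and both became 0 with an estimated correlation and 0 in directional fry. Over the lists past preset camera, the estimated correlation ran from 0.0344 for glycolysis to 0.902 for foamy myeloid cells. It was 0.860 for neurons, 0.454 for T and natural killer cells and 0.216 for scar matrix, against the preset 0.01. Camera's p-value grows with this correlation, so the preset p-values are too small to the extent that these estimates hold. The cause of the other differences was not tested. Abca1, Abcg1 and Apoe kept their direction under all 17 alternatives and passed under none of them. The sign of the Apoa2 log2 fold change, 0.17 with all libraries, reversed without injury replicate 3 (−0.19) and without AZ876 replicate 2 (−0.20), and ranged from −0.196 to 0.477 over the left-out libraries with which it could be tested. No scaling moved the median log2 fold change of all genes by over 0.1. With 3 libraries per group, the simulation found 37.5% of genes changed 2-fold, so smaller changes would mostly be missed.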

Other observations

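The immunoglobulin genes and the tests of explanations, on thinned counts, differences between scores and exchanged labels, were chosen after the results were seen, while the tests of the fixed lists and the counts over other splits were planned. Besides Ighg1, several antibody genes had higher means with AZ876. Igha, the heavy chain of IgA, was at 7.73, 3.73 and 30.4 CPM in the injury libraries and at 23.7, 145 and 98.4 CPM in the AZ876 libraries, a log2 fold change of 2.69 ± 0.86 (SE) with an edgeR adjusted p of 0.330. Jchain, which joins secreted antibody polymers, had a log2 fold change of 2.12 ± 0.74 and Ighg2b one of 2.47 ± 0.80, with AZ876 replicate 1 within the injury range for both. Ighm, the heavy chain of IgM, went the other way at −1.0 ± 0.46. Ighg1 had 2 to 4 counts in each injury library and 30 to 43 in each AZ876 library. The light chain gene Igkc had a log2 fold change of 0.81 ± 0.86 with an edgeR adjusted p of 0.646. None of these genes passed edgeR's adjusted p with all libraries and low-count genes removed, and none was among the DESeq2 calls. In edgeR, Ighg1 passed with no low-count filter, and Ighg1 and Jchain passed without AZ876 replicate 1. Their counts are uncertain to the extent that reads were shared between related genes.

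Cell cycle genes were higher in 26 of 29 cases, with a median log2 fold change of 0.36, and ependymal and cilia genes in 22 of 24, with a median of 0.38. The preset camera adjusted p was 0.000897 for cell cycle and 0.00256 for ependymal genes, and 0.438 and 0.497 with an estimated correlation. For both lists the scores of the groups overlapped (exact permutation p = 0.2 for cell cycle and 0.5 for ependymal genes). The ependymal call was lost without injury replicate 1 (0.172) or AZ876 replicate 2 (0.0964). Endothelial markers were higher in 19 of 22 cases with a median of 0.27, a preset camera adjusted p of 0.00136 and one of 0.430 with an estimated correlation, and Cdh5, which encodes the junction protein VE-cadherin, was at 46.9 ± 7.16 CPM with injury and 70.3 ± 12.4 CPM with AZ876.

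The 6 libraries can be divided into 3 and 3 in 10 ways, so the share of divisions with a result as large can never be below 0.1. For 0 genes past the threshold in edgeR all 10 divisions gave as many or more, as any division must, so this count decides nothing. The highest of the others was 290. For the 178 DESeq2 calls 2 of the 10 did, with 2212 as the highest other, for the 2592 genes at an unadjusted p under 0.05 in edgeR 2 did, with 4620, and for the 35 lists past preset camera 2 did, with 37. These counts are too few for a share under 0.05. The highest values all came from the division that exchanges injury replicate 3 and AZ876 replicate 1. Since they belong to the same division of the same libraries, they are not separate observations. With 10 divisions 1 must be highest, so they do not by themselves show a structure of the samples.

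AZ876 replicate 1 and injury replicate 3 stood next to each other in the middle of the first principal component. With their labels exchanged 5502 genes separated the groups, against 3312 with the deposited labels. That count decides nothing, because these libraries were picked by their place on this component. Of the 52 list scores, 19 separate the groups with the deposited labels and 19 others with the labels exchanged. T and natural killer cells, MHC class II, fibroblasts, scar matrix, Schwann cells and motor neurons are among the former, and neurons, synaptic genes, transmission, complement and foamy myeloid cells among the latter. An exchange of labels and a spread in injury severity or response cannot be told apart from these values, and no marker of identity was tested.

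Lists for T and natural killer cells, MHC class II, fibroblasts, scar matrix and Schwann cells were higher and the neuron list lower with AZ876 in preset camera, each with an adjusted p of 0.430 at an estimated correlation, and the neuron scores of the groups overlapped (exact permutation p = 0.2). Not every injury library was sequenced more deeply: injury replicate 3 held 15493073 counts and AZ876 replicate 3 held 17676466. After thinning to equal totals these lists each kept at least 96.6% of their median log2 fold change. Random thinning keeps each gene's expected share of a library, so little change was likely in advance. The result speaks only to unequal totals as such and draws no wider line on depth. Less spared neural tissue in the AZ876 samples stays open. The T and natural killer cell score less the endothelial score was higher with AZ876 by 1.06 ± 0.30 (SE, exact permutation p = 0.1). It stayed over 2 SE without any 1 library, so these markers were not raised alike. An unequal rise would not decide the question either, because less spared tissue need not raise all other cell types alike, which was not tested. For fibroblasts the same difference was 0.62 ± 0.29 (SE, exact permutation p = 0.1), but 0.36 ± 0.16 without injury replicate 2, and within 2 SE without injury replicate 3 (0.70 ± 0.45) or AZ876 replicate 2 (0.51 ± 0.27). Dorsal root ganglia left on the samples also stay open, as do meninges, lesion size and an effect of AZ876, which were not tested: the Schwann score less the ganglion score was higher by 0.87 ± 0.40 (SE, exact permutation p = 0.2), but 0.56 ± 0.34 without injury replicate 2, and within 2 SE also without injury replicate 1 (0.89 ± 0.63), AZ876 replicate 2 (0.75 ± 0.46) or AZ876 replicate 3 (0.77 ± 0.48).

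Abca1, Abcg1 and Apoe had higher means with AZ876. More lipid-laden myeloid cells in the AZ876 samples stay open as the cause. The score of 24 foamy myeloid genes without LXR targets differed by 0.80 ± 0.41 (SE, exact permutation p = 0.2), within 2 SE, although not without injury replicate 3 (1.02 ± 0.36) or AZ876 replicate 1 (1.11 ± 0.33). The mean of the 3 genes less this score differed by −0.26 ± 0.10 (SE, exact permutation p = 0.1), within 2 SE without AZ876 replicate 2 (−0.27 ± 0.14). Of the single genes, Apoe less this score was beyond 2 SE (−0.38 ± 0.13), and Abca1 (−0.12 ± 0.16, or 0.02 ± 0.13 without injury replicate 2) and Abcg1 (−0.28 ± 0.19) were within it, although Abcg1 was not without AZ876 replicate 1 (−0.42 ± 0.14). LXR activation lasting to week 6 would also raise the 6 lipogenic LXR targets, whose mean score differed by 0.0147 ± 0.128 (SE, exact permutation p = 0.9). That leaves it open, because their distance from the efflux genes, −0.53 ± 0.29, was within 2 SE, although not without AZ876 replicate 1 (−0.70 ± 0.25), and the treatment had ended weeks earlier. Both remain hypotheses, found and tested on the same 6 libraries.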
